A study of Drosophila melanogaster with 2 samples.

How the data were processed

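RNA recovered with tra2 from S2R+ cells was measured in 2 libraries, labelled as biological replicates 1 and 2 of 1 experiment. Both were assigned to a single group from the labels' descriptions. RNA was fragmented chemically and sized above 200 bases, per the labels. For each library the authors deposited a track of normalized signal of all reads on dm3, derived from that library's own alignment, per the text files deposited beside the tracks. The aligner, its settings, the treatment of reads with several placements and of duplicate reads are not given in the sources used here. Each library has a single track of all reads, with no strand, so antisense and overlapping transcripts cannot be separated.

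The deposited signal is coverage, the number of reads over each base per 1000000 aligned reads. This was tested on the values: all of them (100%) were whole multiples of the smallest, within 1e-06 of a step. Depth summed over bases and divided by 50 gave 3482038 reads in replicate 1 and 7280416 in replicate 2, exactly 1000000 over the smallest value. A single read was therefore worth 0.287 RPM in replicate 1 and 0.137 RPM in replicate 2, and reads were 50 bases long. Because the scale is per 1000000 of all aligned reads, a pile that takes a large share of a library lowers every other value in it. The deeper replicate 2 has the smaller counting error.

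The plan, written before the data were examined, used genes where an annotation of dm3 was given and 1 kb windows otherwise. The reference table used here is of Release 6, another build, so positions were not converted and genes were not named. The planned exonic share, gene lists and signal on tra2 itself were not analysed here. Each window's value was its mean signal per base. Shares per sequence came from summed depth, with 95% Wilson intervals. Agreement used log2(signal + 0.000862 RPM), a pseudocount of 0.01 times the median nonzero value, over windows with signal in at least 1 replicate. A window counted as present with at least 1 read. Windows over the median signal were called different at 2-fold. There is no control group, and with 1 library on each side no test across windows was made. Nothing in the labels beyond the words biological replicate says how the cultures were separated.

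The windows named were chosen by a rule fixed before the data were examined: the 10 highest whose replicates differed by less than 2-fold, at least 5 kb apart; the highest such window of each sequence; and the 5 with the largest ratio in each direction among windows over the median signal, at least 5 kb apart. Other windows, the X to autosome ratio, the matched lists for the mitochondrial genome and the gap search were chosen after seeing the data. Matched lists drew, for each mitochondrial window, 1 of the 200 arm windows nearest to it in rank of signal. For summed signal, each drawn window was scaled to the signal of the window it stood for. Counting intervals of read ratios are exact binomial, on reads rounded up.

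The window and gap code was tested on simulated data. It recovered 18 of 18 made-up introns with 0 false gaps. Those reads were laid at random positions, without stacked copies or uneven coverage, so this does not measure false gaps in the real tracks. A simulation of replicate 1 against replicate 2 over 45070 windows had counting error only. Of 200 windows over the median that were raised 4-fold in replicate 1, 197 passed the 2-fold limit. An excess in replicate 2 and changes of other sizes were not simulated. Alternatives covered the scaling, pseudocount, low-signal filter, sequences used, window size, detection minimum, fold, number of top windows and leaving out each replicate. Thinning replicate 2, leaving U and XHet out of the totals and drawing matched lists from the 20 nearest windows were added after seeing the data. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.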

Results

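The series measured RNA bound to the splicing regulator tra2 by RNA immunoprecipitation and sequencing (RIP-seq). In this assay an antibody pulls a protein out of a cell lysate, and the RNA that comes with it is sequenced. The product of tra2 is an RNA-binding protein known for directing sex-specific splicing of doublesex. The cells were S2R+, an established Drosophila melanogaster line of embryonic origin. They carried FLAG- and HA-tagged copies of tra2 behind the promoter of MtnA, a metallothionein gene that copper switches on, and received 0.35 mM copper sulfate for 24 h. The labels give the antibody only as tra2, so it is unknown whether either tagged form, both, or the cells' own protein was precipitated. They also name a possible control experiment, which was not analysed here. The data comprised 1 group of 2 biological replicates, with no control or input library, so the only comparison was between the replicates. Without such a library, signal at a locus reflects both the abundance of its RNA and its recovery with tra2, and no value below is an enrichment. Replicate 1 held 3482038 aligned reads and replicate 2 held 7280416. All positions are 1-based dm3 coordinates, and windows are described by position because no annotation of that build was used.

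Most of the aligned reads lay outside the chromosome arms, in a few narrow piles. The unplaced sequence U took 59.7% ± 0.0162 of the aligned reads (SD, n = 2) and the X heterochromatin, XHet, took 11.9% ± 3.58. The 6 arms 2L, 2R, 3L, 3R, 4 and X together took 27.5% ± 3.27, the mitochondrial genome M 0.706% ± 0.264, and the 4 autosomal heterochromatin sequences 0.166% ± 0.0239. Without the 100 highest 1 kb windows U took 1.32% and XHet 0.206% of the remaining reads, so the ranking rested on windows among these. Few of the 100 highest windows of each replicate lay on these sequences. In replicate 1, 16 lay on U and 3 on XHet, and in replicate 2, 18 and 3. The share on U was 59.74% in replicate 1 and 59.72% in replicate 2, with overlapping 95% Wilson intervals of 59.69 to 59.79% and 59.68 to 59.75%. The share on XHet differed far more, at 9.40% (95% Wilson interval 9.37 to 9.44%) in replicate 1 against 14.46% (14.44 to 14.49%) in replicate 2. The mitochondrial share differed the other way, at 0.893% (0.883 to 0.903%) against 0.520% (0.514 to 0.525%). The Y heterochromatin held 5 reads in replicate 1 and 18 in replicate 2. These intervals cover counting error only, since amplified copies of a fragment are not independent molecules.

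**Figure D1:**
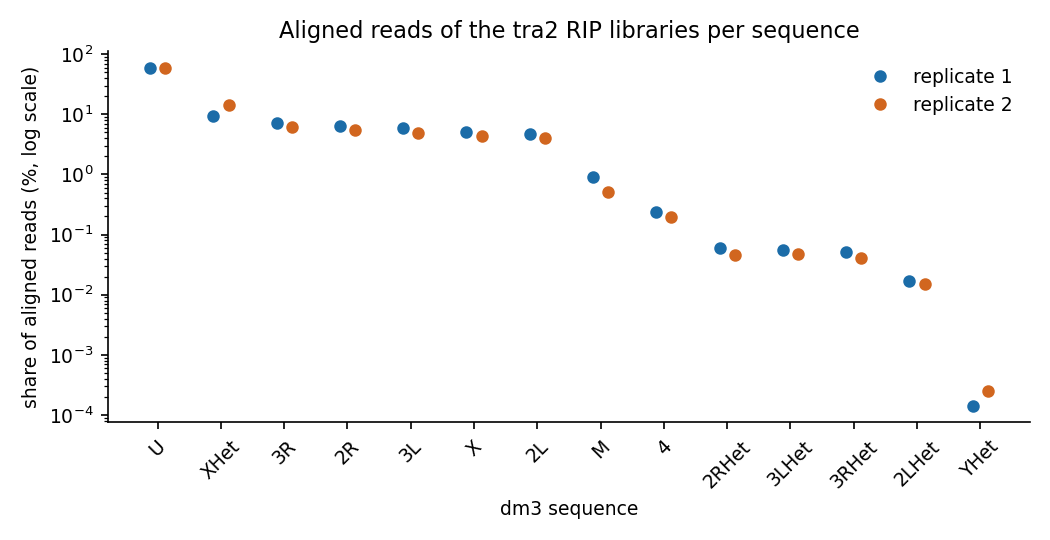
Share of aligned reads (percent, log scale) on each of the 14 dm3 sequences, ordered by the mean of the replicates; each point is 1 library. U took 59.74% and 59.72% in replicates 1 and 2, while XHet took 9.40% and 14.46%, and M 0.893% and 0.520%.

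The signal on U and XHet lay in narrow piles. In replicate 1, 1013 bases held 90% of the signal of these sequences, of 51372 covered bases, and in replicate 2 it was 998 of 62066. On the arms the same 90% took 6709155 and 7632305 bases. The highest 1 kb window of the genome, U 5727001 to 5728000, held 28.5% of all reads in the mean of the replicates, with a mean signal of 14240 ± 205 RPM (reads per 1000000 aligned reads) per base (SD, n = 2). U 9063001 to 9064000 followed with 4036 ± 108 RPM, although reads covered only 73 of its 1000 bases in either replicate. The highest depth there was 275705 reads in replicate 1 and 598758 in replicate 2. The other U windows among the 10 highest started at 9660001, 6962001, 4571001, 3545001, 8839001 and 9578001. Their mean signals ran from 2542 down to 448 RPM, and the replicates of each differed by at most 1.21-fold. Windows closer than 5 kb to a higher one were passed over in this choice. Among them, U 9064001 to 9065000 carried 1603 RPM in replicate 1 and 2291 RPM in replicate 2, a 1.43-fold difference, and ranked above the window at 4571001. XHet 194001 to 195000, with 970 ± 97.9 RPM, ranked above the one at 3545001. XHet supplied a pair of windows. XHet 184001 to 185000 carried 1536 ± 85.9 RPM. XHet 191001 to 192000 carried 2305 RPM in replicate 1 and 4569 RPM in replicate 2, a 1.98-fold difference. The ribosomal RNA genes of this species lie in X and Y heterochromatin as textbook background, but the identity of these piles was not examined, because no genome sequence was used.

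**Figure D2:**
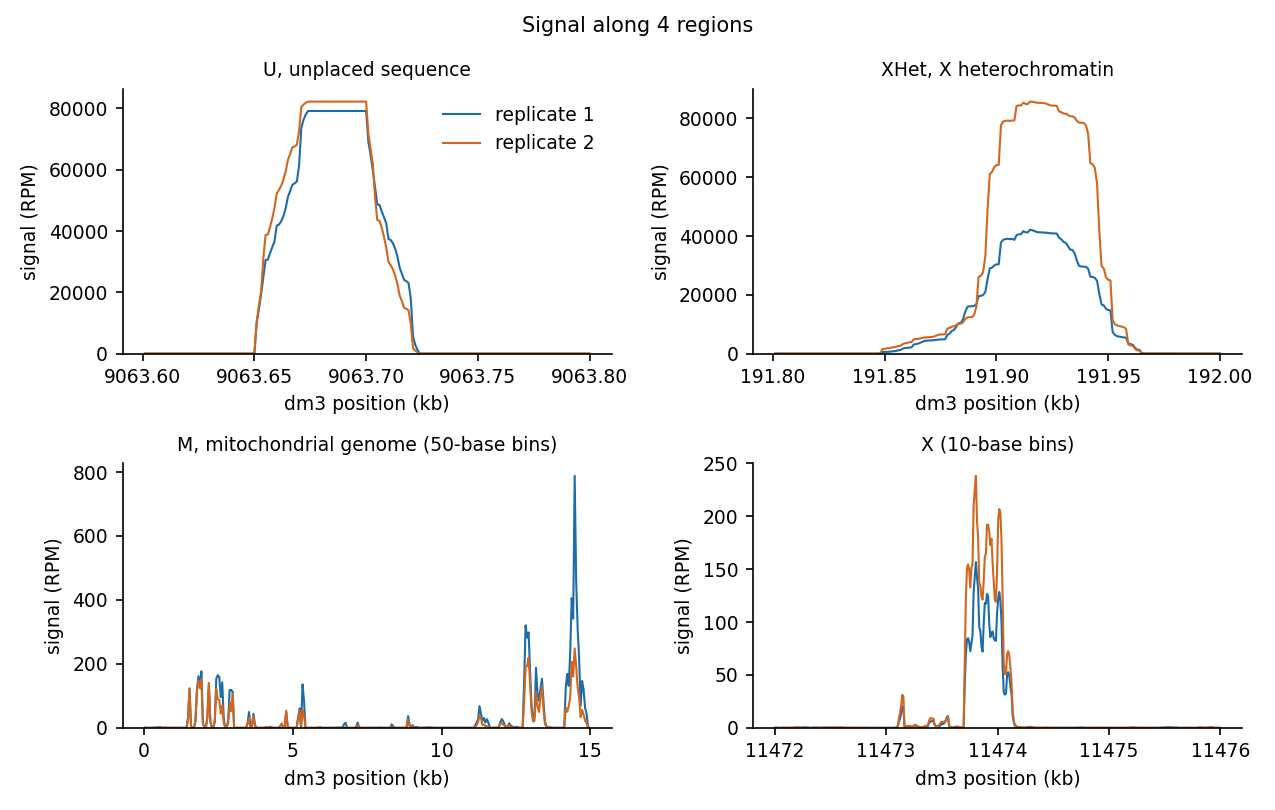
Signal (RPM, linear axes from 0) along 4 regions against dm3 position in kb, 1 line per replicate. The U pile shown had nearly the same height in both libraries. The XHet pile and the X locus were higher in replicate 2, and the mitochondrial peak between 14001 and 15000 was higher in replicate 1.

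On the chromosome arms the highest window of each arm, the same window with or without the 2-fold limit on its replicates, differed by at most 1.19-fold. Over the 100 highest arm windows the replicates differed by a median of 1.13-fold and at most 1.62-fold, at X 11474001. 2L 10201001 to 10202000 had the highest arm signal, 87.8 ± 2.30 RPM (SD, n = 2). It was followed by 3R 5609001 to 5610000 with 69.8 ± 2.48 RPM, X 5325001 to 5326000 with 66.9 ± 8.10 RPM, 2R 20856001 to 20857000 with 66.1 ± 5.36 RPM, and 3L 3195001 to 3196000 with 64.2 ± 6.48 RPM. The differences among the windows of 3R, X, 2R and 3L were smaller than the replicate SD of the X window. Within each library, however, the 3R window lay above that of 2R, and 2R above 3L. Only the X window changed place, from the highest of these in replicate 1, with 72.7 RPM, to below 2R in replicate 2, with 61.2 RPM. The highest window of chromosome 4, at 1054001 to 1055000, had 7.08 ± 0.294 RPM. The highest windows of the autosomal heterochromatin sequences were lower still, from 5.60 ± 0.515 RPM on 3RHet, through 3.84 ± 0.0574 on 3LHet and 3.55 ± 0.235 on 2LHet, to 2.68 ± 0.349 on 2RHet. On YHet the highest window, at 328001 to 329000, rested on 4 and 15 reads.

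Per megabase up to the last covered base, X carried 0.906 ± 0.00419 times the signal of 2L, 2R, 3L and 3R together (SD, n = 2). The ratio was 0.909 in replicate 1 and 0.903 in replicate 2. Chromosome 4 carried 0.691 ± 0.0149 times the signal of those arms. Among single arms, 2R had the highest density, 2832 ± 334 RPM per megabase, and 2L the lowest of the large arms, 1912 ± 216. In each of these 4 arms and X replicate 1 lay above replicate 2 by 1.17- to 1.19-fold.

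The mitochondrial genome, which encodes ribosomal RNAs, transfer RNAs and subunits of the respiratory chain, had more signal in replicate 1. Of its 15 windows, 14 were higher in replicate 1. So were 87 of the 100 highest arm windows, so the direction alone does not set the mitochondrial windows apart. Their median log2 ratio was 0.82. No list among 10000 random lists of arm windows nearest in rank of signal had so high a median, as a description of these libraries (upper limit of their central 95%, 0.37). The mitochondrial windows adjoin on 1 sequence and may vary together, while arm windows were drawn independently, so this limit can be too narrow. The match is loose for the strongest windows, because the 200 highest arm windows reach from 87.8 down to 6.68 RPM and 1 mitochondrial window lies above them all. The window from 14001 to 15000 carried 181 RPM in replicate 1 and 73.9 RPM in replicate 2. Without it the mitochondrial shares were 0.530% and 0.372%. The next highest, from 2001 to 3000, carried 55.8 ± 14.7 RPM (SD, n = 2) and is the highest mitochondrial window whose replicates were within 2-fold.

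Over 1 kb windows, 45070 had signal in at least 1 replicate and 31417 (69.7%) had at least 1 read in both. Across windows, which are not independent replicates, log2 signal correlated with a Pearson r of 0.790 and the signal with a Spearman rho of 0.90. The r was 0.977 among the 4507 windows with the highest 10% of signal. The median absolute log2 ratio over all windows was 0.73. The chi-square of the read counts over its degrees of freedom was 1.41 over 22179 arm windows above the median signal. The libraries were kept as 2 replicates because the labels call them biological replicates, which this value does not test. The 100 highest windows held 74.2% of the signal in replicate 1 and 78.3% in replicate 2, although most of them lay on the arms.

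**Figure D3:**
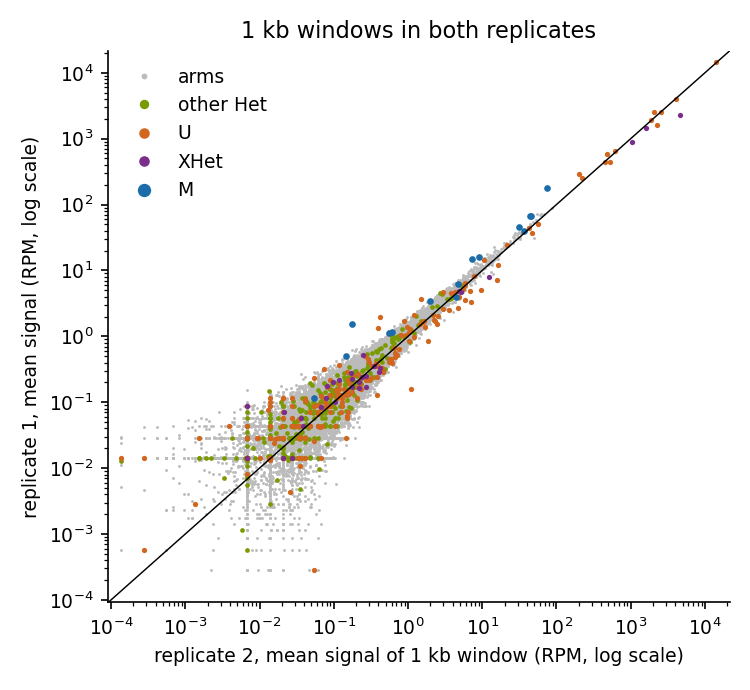
Mean signal of each 1 kb window with signal in both libraries, replicate 1 against replicate 2 (RPM, both axes log scale), coloured by sequence; the line marks equality. Windows over the median signal lie above the line by a median log2 ratio of 0.27. Of 15 mitochondrial windows 14 lie above it, as do 87 of the 100 highest arm windows.

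Of the 22534 windows over the median signal of 0.0547 RPM, 2001 (8.88%) differed by 2-fold or more between the replicates, 1598 higher in replicate 1 and 403 higher in replicate 2. Over all windows with signal the majority turned, with 8263 of 18174 such windows higher in replicate 1. That count includes windows with no signal in 1 replicate, which 1 read in the other puts past 2-fold at this pseudocount. The deeper replicate 2 had at least 1 read in 39855 windows, against 35289 in replicate 1. The turn is therefore not read as a reversal of direction. The windows over the median had a median log2 ratio of 0.27 in favour of replicate 1. Relative to that shift 1610 windows were 2-fold apart, split 776 to 834. Libraries simulated with counting error alone at these depths, and no shift between them, put 1566 of 22241 unchanged windows (7.04%) past 2-fold. The count to set beside this is the 1610 of 22534 relative to the shift, a nearly equal share, not the 2001. In the highest 10% of windows 20 were 2-fold apart before centring, against 0 among 4410 unchanged windows of the simulation. The SD of the log2 ratio there was 0.27, against a median counting error of 0.20. An SD weighs extreme windows and a median does not, so the gap between these values does not measure excess spread.

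The windows that differed most were thinly covered. The 5 with the largest excess in replicate 1 lay at 2L 19424001, 2RHet 2359001, 3R 23096001, 3L 16373001 and chromosome 4 217001. They held 9 to 10.7 reads in replicate 1 and 1 to 2 in replicate 2. The 2L window had a ratio of 22.5 with an exact 95% counting interval of 3.34 to 989.96, and the chromosome 4 window 9.41 with an interval of 1.95 to 89.5. The 5 with the largest excess in replicate 2 lay at 2L 21809001, 3R 17308001, 2L 3715001, U 9503001 and 2R 15518001. All but the U window had at most 1 read in replicate 1. The U window held 11 reads in replicate 1 and 158 in replicate 2, a ratio of 0.146 with an exact 95% counting interval of 0.0712 to 0.268. Its reads covered only 53 and 52 bases, and the highest depth equalled the number of reads in each replicate. They thus lay in 1 stack, and the interval, which takes reads as independent, does not cover amplified copies. No p-value is given, since each replicate is 1 library and these windows are the extremes of 22534.

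The arms also held gaps with sharp edges at the same bases in both libraries. At 1178 places the depth fell within 1 base by at least 10 reads and to at most 50% in both replicates, and rose again in the same way 40 to 2000 bases downstream. By arm, 298 lay on 2R, 291 on 3R, 242 on 3L, 172 on 2L, 172 on X and 3 on chromosome 4. The median gap was 86 bases long (quartiles 64 and 308), the most frequent length was 64 bases, and 504 gaps (42.8%) measured 55 to 75 bases. Depth inside the gaps averaged 1.55% ± 0.133 of that in the 20 bases on either side (SD, n = 2), a value bounded by the 50% limit used to find them. The deepest gap lay at 3R 5609682 to 5609945. Depth there fell by 1213 reads and rose by 1220 in replicate 1, and by 2431 and 2453 reads in replicate 2. The gap at 2L 10201529 to 10201598, inside the highest arm window, had falls of 438 and 894 reads and rises of 424 and 897.

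**Figure D4:**
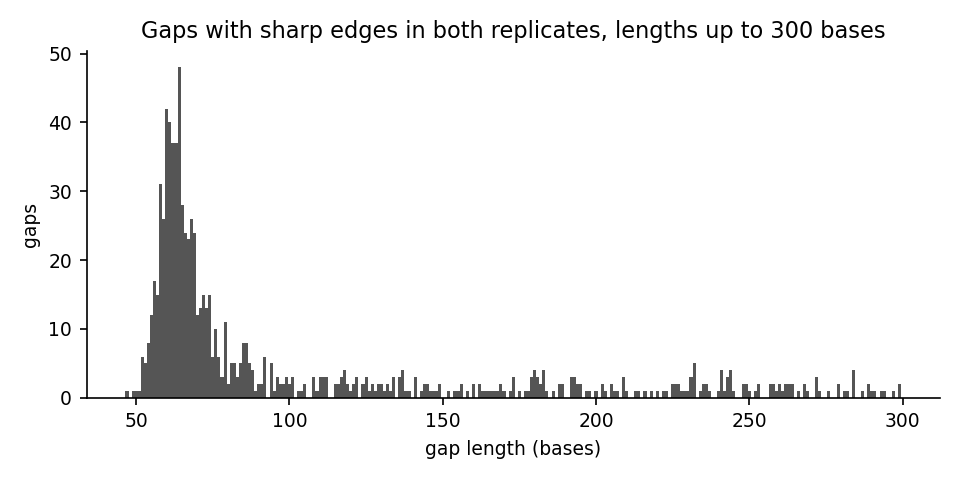
Number of gaps (vertical axis) by gap length in bases (horizontal axis, lengths up to 300) for gaps with sharp edges in both replicates. The counts peak at 64 bases, and 504 of all 1178 gaps lie between 55 and 75 bases.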

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

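Scaling to equal totals changed nothing, since the deposited values already have equal totals. The Pearson r of 0.790 became 0.782 after centring the log2 ratios, 0.932 and 0.607 with a pseudocount 10 times larger and smaller, 0.941 over windows above the median, 0.594 and 0.920 with windows of 200 bases and 5 kb, and 0.715 with replicate 2 thinned. Windows with a read in both replicates numbered 16141 at a minimum of 10 reads, and 86587 and 10793 with windows of 200 bases and 5 kb. Windows 2-fold apart numbered 18174 without the filter on signal, of which 8263 were higher in replicate 1, a minority; 20 in the highest 10%, of which 16 were; and 146 at 4-fold, of which 116 were. Centring gave 1610, of which 776 were higher in replicate 1, and leaving out U and XHet 1538, of which 723 were higher in replicate 1, against 1598 of 2001 as deposited. The top windows held 67.1% for 10 and 83.9% for 1000. Ranked anew within the arms, the 100 highest arm windows held 17.97% of the arms' signal, and ranked anew without U and XHet, the 100 highest held 19.2% of the rest. Leaving out either replicate gave 74.2% and 78.3%, kept U between 59.72% and 59.74%, and X against the large autosomal arms between 0.903 and 0.909. Without the 100 highest windows of all sequences U fell to 1.32% and the X ratio was 0.886. The arms-only setting gives no value for U. The gaps numbered 488 at 20 reads per step and 1150 when depth had to fall to 20%. Smaller windows hold fewer reads each, and stricter minima keep fewer windows or gaps, by construction. Windows with no signal in 1 replicate take the pseudocount as their value there, so r depends on it by construction. The same windows enter the count of 18174 without the filter on signal. The cause of the other changes was not tested. No paired analysis was possible because there is 1 group. Alternatives on exons, gene lists and tra2 were not run. Depth limited the comparison of weak windows, as counting error alone put 7.04% of simulated unchanged windows over the median past 2-fold.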

Other observations

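The tests on the overall shift and on the mitochondrial windows were chosen after their results were seen, while those on the gaps were set before. Among 297 arm windows with at least 1000 reads, summed over both replicates, the log2 ratio of replicate 1 over 2 had a median of 0.19 and an SD of 0.20. In 3 of them it lay over 3 SD from that median, each time on the side of replicate 2. X 11474001 to 11475000 and the adjoining X 11473001 to 11474000 had ratios of -0.69 and -0.66, with 8.78 and 31.3 RPM in replicate 1 and 14.2 and 49.6 RPM in replicate 2. High signal ran unbroken across the boundary of these windows, so they count as 1 locus. The remaining window, 3L 1668001 to 1669000, had a ratio of -0.46, with 9.59 RPM in replicate 1 and 13.2 RPM in replicate 2. They were named after their values were seen.

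The gaps with sharp edges may be introns crossed by split alignments, which predicts that islands of a single read shorter than 50 bases come as neighbouring pairs whose lengths sum to a whole read. Such short islands numbered 7029 in replicate 1 and 5634 in replicate 2, and not all had a short neighbour. Of 2125 neighbouring pairs in replicate 1, 1941 summed to exactly 50 bases, and of 1466 in replicate 2, 1316 did. Median distances between the parts of these were 65 and 66 bases. The number at the exact sum was 606.6 times the mean number per single sum 1 to 5 bases off in replicate 1, and 411.2 times in replicate 2. These islands hold 1 read each, while the gaps need steps of at least 10 reads. The sums therefore show split alignments in the tracks, not at each gap. Stacked copies of whole reads are argued against, since these would put a step in depth 50 bases before the fall or after the rise, which had a median of 0 as a share of the step at the edge on both sides in both replicates, and reached 50% of it at 8 to 10 of 1178 gaps. Which genes the gaps belong to, and whether tra2 acted on them, was not tested.

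The median log2 ratio of 0.27 in favour of replicate 1, over windows above the median signal, is not all accounted for by the larger share of the window at XHet 191001 in replicate 2, as it stayed at 0.1967 once that window was left out of both totals. Leaving U and XHet out of both totals brought it to 0.01182, which decides nothing, since 99.25% of these windows lie on the sequences left in, which the new totals centre by construction. The joint share of U and XHet was 5.03 percentage points higher in replicate 2, of which the window at XHet 191001 made up 4.53. The share of U as a whole was nearly equal, at 59.74% in replicate 1 and 59.72% in replicate 2. Single windows of U moved both ways. From replicate 1 to replicate 2, U 9064001 went from 3.21% to 4.58% and U 6962001 from 5.06% to 4.17%. Per arm read, U had 2.01 reads in replicate 1 and 2.37 in replicate 2. Why these shares differed stays open, since uneven removal of an abundant RNA and uneven background in the immunoprecipitation would look alike. No biological explanation was tested, because the design has 1 group.

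The mitochondrial excess in replicate 1 was larger than this shift. Mitochondrial over arm reads were 1.45 times as high in replicate 1, with a lower 95% counting limit of 1.43. This argues against counting error of independent reads only. The limit takes each read as a separate molecule and the arm counts as fixed. It cannot decide on the sampling of few molecules that were then amplified. An excess remained without the single window at 14001, as the summed signal of the other 14 windows had a log2 ratio of 0.5124. The upper limit of the central 95% of random lists was 0.3581, and 0.257 when lists were drawn from the 20 nearest arm windows. Both limits can be too narrow, because the lists draw arm windows independently. In summed reads the excess over the arms was 0.54 on the log2 scale with the window at 14001 and 0.27 without it. A difference in mitochondrial RNA carried through the preparation stays open and was not tested.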
